A study of Homo sapiens with 20 samples.

How the data were processed

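Vessels captured by laser microdissection from human breast tumors and from normal breast were profiled on 2-colour oligonucleotide arrays. Per the labels, the Cy3 channel held reference RNA and the Cy5 channel the breast specimen on every array, so all ratios run the same way and no dye swap balances a dye effect. The labels name the tumor specimens with the word luminal and a letter and the normal specimens with a letter. The letters A to E were read as names of specimens and not as tumor subtypes. Each specimen has a first array and a technical repeat. No scanner output was used. The authors deposited 1 table of log ratios, read here as the log2 of specimen over reference. Its method of background correction and normalization is not given in the sources used here. The log base is not stated. A log10 scale was ruled out, because the largest value, 9.76, exceeds 4.82, the highest log10 ratio that 16-bit signals allow. A natural log was not ruled out, and under it every difference would stand for a larger fold. Whether the arrays were centred is not stated. The median log2 ratio of the first and the repeat array was 0.027 and 0.016 for tumor specimen A, 0.029 and 0.026 for B, 0.014 and 0.018 for C, 0.032 and 0.048 for D and 0.021 and 0.016 for E. For the normal specimens it was 0.058 and 0.069 for A, 0.005 and 0 for B, 0 and 0 for C, 0.006 and 0.001 for D and 0.024 and 0.029 for E. The direction was taken from the dyes in the labels.

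The probe table used here lists 29130 of the 44290 probes, 29033 of them with 1 gene symbol and 97 with several, and 15160 spots are unnamed here. Probe IDs of that table did not match the row IDs of the value table. When they were taken as equal, r of the mean log ratios over 18085 pairs of probes of the same gene was 0.01, and 307 of the 462 spots of a repeated control probe carried a gene name. The rows were therefore matched through the geometry of the array, without reference to the groups. The value table was read as 430 rows of 103 spots and the probe table as 206 columns of 215 staggered spots numbered from the opposite corner. This gave r of 0.465 over the same pairs, with 0 of the 462 control spots carrying a gene name. The highest r among the other layouts of the 14 scored was 0.011, among 100 random orders 0.022, and among 6000 offsets and 7984 plain rearrangements 0.029. The layout is an inference from the values and is documented in none of the sources used here, and every gene name in the text depends on it. Gene IDs of 28992 probes were found in the gene table of the reference, and 0 symbols changed.

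The 462 control spots and 69 probes of genes on the Y chromosome and of X inactivation transcripts were left out. Probes with 1 symbol were averaged per gene, and other spots were kept singly, which gave 32755 features, 17960 genes and 14795 unnamed spots. Among 7399 genes with more than 1 probe, 24 had 1 probe higher and another lower at an unadjusted p under 0.05. Averaging lowers the difference of a gene where 1 probe responds and another stays near 0. In the alternative with single probes, a named gene takes the value of its probe whose mean log ratio over the specimens lies farthest from 0, called the probe farthest from the reference. The arrays of a specimen were averaged before any test, so n is 5 per group. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over the features and a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with camera at an estimated correlation and with fry. Means of a list, the separation of the groups and the spread between specimens were tested by exact permutation over the 252 arrangements of the specimens. Files were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

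The 26 lists, the tests and the rule for naming genes were fixed before the data were examined. The lists cover pan-endothelial, capillary lipid handling, mural cell, fibroblast, tumor stroma matrix, vascular basement membrane, tumor endothelial, angiogenic, leukocyte adhesion, luminal and basal epithelial, adipocyte, myeloid, lymphocyte and plasma cell, mast cell, erythrocyte and platelet, cell cycle, Wnt, JAK-STAT, sphingolipid, protease, interferon, hypoxia, immediate-early, oxidative phosphorylation and ribosomal protein genes. Genes named are the 12 with the largest difference in each direction among those that passed with groups that do not overlap, filled up with the genes of the smallest p where fewer passed, up to 4 members of each list with the smallest p, and SFRP2, JAK3 and SMPD3, recalled as followed up by the study.

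The fit was tested on simulated data with the spread of the real specimens. The 200 changed features among 32755 were drawn from those with an SD within groups above the median. Of these, limma recovered 8% of those changed 2-fold, 84% of those changed 4-fold, 88% of those changed 8-fold and 90% of those changed 16-fold, with 7 calls among unchanged features. Features were simulated as independent of each other, so these rates do not cover correlation between features. They also depend on the number of changed features simulated. The simulated fit made 142 calls in all, and more calls ease the adjusted threshold. The real fit made 1 call under a stricter effective threshold, so the rates do not describe its power. A list with a simulated inter-gene correlation of 0.3 and no group difference reached p under 0.05 in 47 of 100 simulations with the preset correlation, in 5 with an estimated correlation and in 4 with fry. Alternatives covered the scaling between arrays, single arrays, all arrays with the specimen as a random block, a filter on features of small spread, single probes, a replicate block, array weights, other tests and thresholds, and leaving out each specimen. Alternatives for missing values were not run, since the table has none.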

Results

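Gene expression was measured in small blood vessels taken from human breast tissue by laser capture microdissection, in which chosen structures are cut from a tissue section under a microscope. The specimens formed 2 groups, with 5 specimens of tumor vessels and 5 specimens of vessels from normal breast. RNA of each specimen was labelled with Cy5 and hybridised with Cy3-labelled common reference RNA on 2 arrays, the repeat array being a technical repeat, which gave 20 arrays. Each array carried 44290 spots, none of them without a value. The value analysed is the log2 ratio of the specimen to the reference, and n is 5 specimens in each group with the arrays of a specimen averaged. The labels do not say whether the specimens came from different people, so the tests below measure the spread between specimens. The number of specimens limits the precision of every value. No brightness values were analysed here, so it is not known which spots were close to background. Gene names were assigned by a spot layout that was inferred from the values, as the processing account describes, and each named gene rests on it.

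The comparison of the groups asked which genes differ between the vessels of breast tumors and those of normal breast. ZNF177, a zinc finger gene, rose in the tumor vessels. Its log2 ratio was 3.31 ± 0.37 (SD, n = 5) in tumor and 1.47 ± 0.18 (SD, n = 5) in normal vessels, a difference of 1.84 (SE 0.19), or 3.57-fold if the unit is log2, with a limma adjusted p of 0.0329. It was the 1 feature of 32755 that passed, and 0 features fell. At an unadjusted p under 0.05 limma counted 3886 features, or 11.9% of those tested, of which 1575 were higher and 2311 lower in tumor vessels. All 5 tumor specimens lay above all 5 normal specimens for 287 features and below them for 501, together 2.41% of features where chance gives 0.794% for features that vary independently. Regrouping the specimens also gave many features at an unadjusted p under 0.05, with as many as in the real groups in 5 of 100 splits, the real one included. The other splits had a median of 1277 and a highest count of 4972. The split with 4972 kept 4 tumor specimens on 1 side, and the next highest, with 4695, kept 3. At an adjusted p under 0.10, a wider threshold set as an alternative, 37 features were higher and 93 lower, and 55 of these 130 carried a gene name. Leaving out tumor specimen B raised the count at 0.05 from 1 to 121 features, 30 higher and 91 lower, while a model of all 20 arrays with the specimen as a random block, whose degrees of freedom count arrays and not specimens, called 1284, and quantile normalization called 2, both lower. The call of ZNF177 was lost when tumor specimen A or C or any 1 of the 5 normal specimens was left out, with adjusted p up to 0.188. It was also lost at equal array spread (0.102), on the first arrays alone (0.0945), under quantile normalization (0.0918), with the specimen letter as a block (0.0883), with each probe on its own (0.0754), and by an ordinary linear model and an adjusted p under 0.01, each of which called 0 features. An exact rank test also called 0 features, but it could not call any. Its smallest p at 5 against 5 specimens, 0.00794, cannot pass over 32755 features with only 287 and 501 of them separated.

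The other genes with the smallest p did not pass at 0.05 and are given as values. Among those higher in tumor vessels were CILP, a cartilage matrix protein, with a difference of 3.61 (SE 0.51), and CCL19, a chemokine that attracts T cells and dendritic cells through CCR7, with a difference of 3.20 (SE 0.56). NOD2, an intracellular sensor of bacterial peptides, differed by 2.67 (SE 0.39). NOX4, a subunit of an NADPH oxidase, differed by 2.37 (SE 0.41), and both of its probes gave 2.27 or more. LAMB1, the laminin beta-1 chain, differed by 1.86 (SE 0.32), ARHGAP4 by 1.66 (SE 0.30), ATG16L2 by 1.64 (SE 0.28), DHX58, an RNA helicase of the antiviral response, by 1.55 (SE 0.27), CACNA2D4 by 1.46 (SE 0.22), MICAL1 by 1.05 (SE 0.18) and the noncoding RNA OSER1-DT by 0.87 (SE 0.15). Among those lower in tumor vessels, RGS2, a regulator of G protein signaling, showed the widest gap, with a difference of -3.65 (SE 0.65). SPRY2, an inhibitor of growth factor receptor signaling, differed by -2.19 (SE 0.35) and VSNL1 by -1.62 (SE 0.24). RPL36, a ribosomal protein gene, differed by -1.49 (SE 0.27), OCA2 by -1.23 (SE 0.21), RPL10L by -1.18 (SE 0.22), BTF3 by -1.10 (SE 0.20), ESD by -1.09 (SE 0.18), TM4SF1 by -1.08 (SE 0.15), RNF150 by -1.04 (SE 0.19), CHPT1 by -1.03 (SE 0.19) and PTRHD1 by -1.02 (SE 0.18). In each of these 23 genes the tumor and normal specimens did not overlap, and the limma adjusted p lay between 0.0857 and 0.0960. Under quantile normalization RPL10L differed by -0.66 (adjusted p 0.527) and ESD by -0.68 (adjusted p 0.293), and the probe of TM4SF1 farthest from the reference gave -0.65 (adjusted p 0.392).

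**Figure D1:**
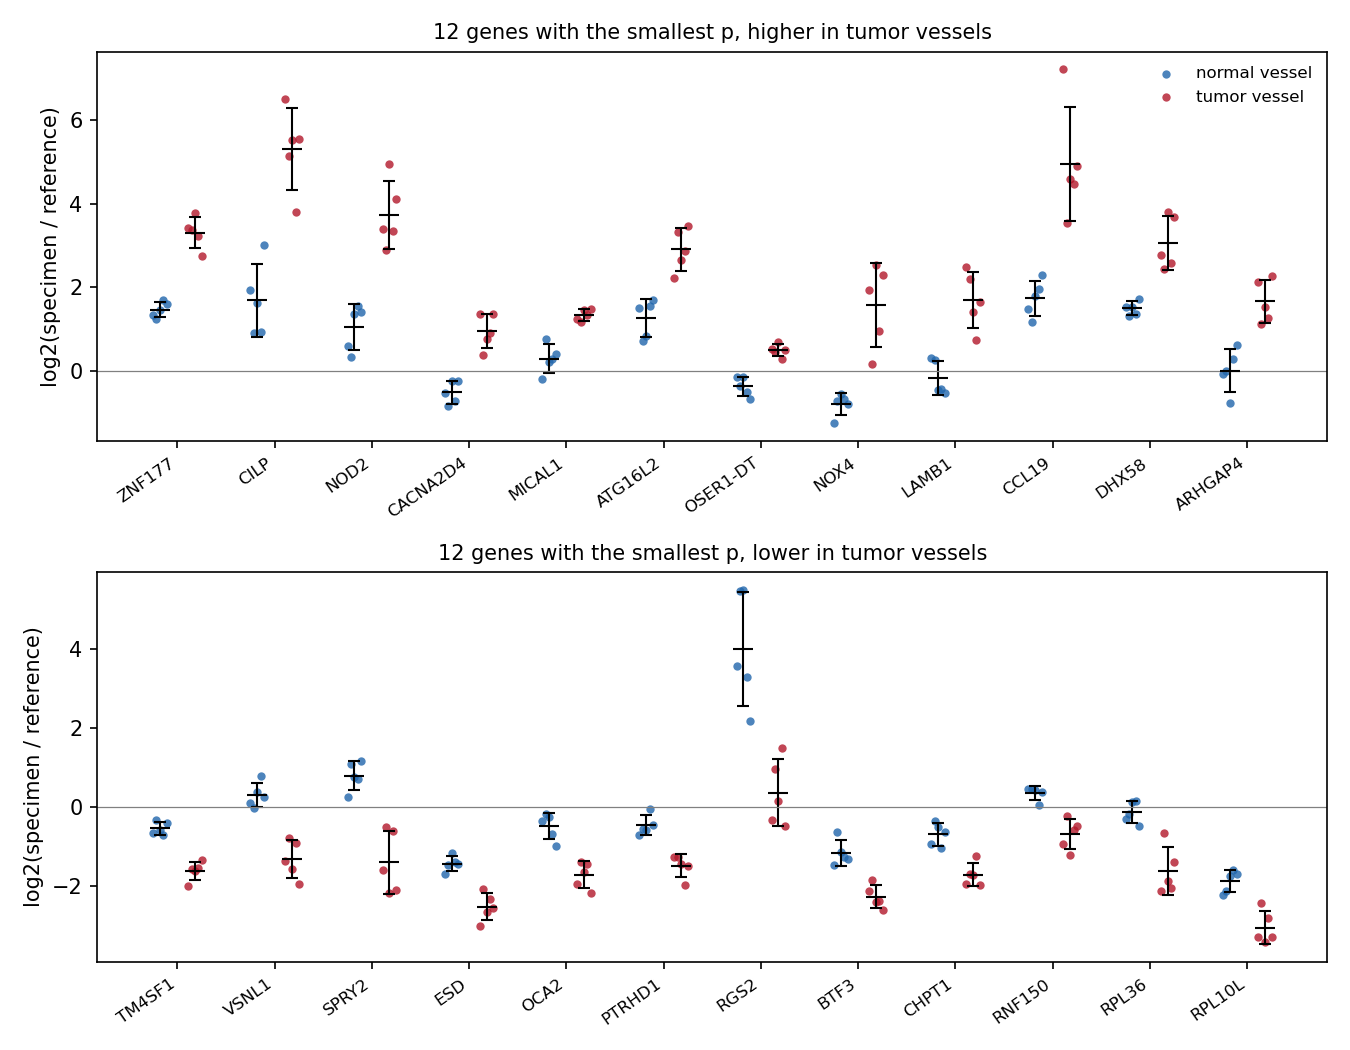
Log2 ratio to the reference RNA (vertical axis) of the 12 genes with the smallest p in each direction. Each dot is 1 specimen, the bars give the group mean and SD over 5 specimens, and of these genes ZNF177 passed at an adjusted p of 0.0329.

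Of 26 gene lists fixed before the data were examined, camera with its preset inter-gene correlation called 13, with 9 higher and 4 lower in tumor vessels relative to all other features. With an estimated correlation 0 of the 13 calls held. By fry's directional test 1 list passed, the ribosomal proteins, with an adjusted p of 0.0263. Without tumor specimen A or E camera called 8 lists. An exact permutation test of each list's mean (2-sided) gave p under 0.05 for 8 of the 26 lists. Among the called lists it gave p = 0.00794 for ribosomal and immediate-early genes, 0.0159 for tumor stroma matrix and tumor endothelial genes, 0.0397 for basal and interferon genes, 0.0873 for basement membrane genes and for proteases, 0.103 for pan-endothelial, 0.119 for fibroblast, 0.167 for oxidative phosphorylation, 0.183 for myeloid and 0.238 for lymphocyte genes. Among the lists not called by camera it was 0.0159 for Wnt signaling and 0.0317 for mast cell markers, both lower in tumor vessels. After Benjamini-Hochberg adjustment over the 26 lists these p ran from 0.0825 to 0.344, and 0 passed. The adjusted p with an estimated correlation is given beside each of these 13 calls below, and apart from ZNF177 no named gene passed over all features.

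Genes of the matrix that surrounds tumors stood higher in the tumor vessels. The list of tumor stroma matrix genes had a median difference of 1.14, with 27 of 30 members higher and a camera adjusted p of 1.44e-12 (adjusted p = 0.270 with an estimated correlation). Over the list alone, 11 members passed as higher and 0 as lower, and the other 19 did not pass. The list mean was 1.70, 1.39 and 1.96 in tumor specimens A, C and E, 0.40 in tumor specimen B and 0.07 in tumor specimen D, against -0.26 to 0.29 in normal vessels. COL10A1, a short-chain collagen, had a log2 ratio of 4.15 ± 1.80 (SD, n = 5) in tumor and 0.72 ± 0.27 (SD, n = 5) in normal vessels. FAP, a protease of activated fibroblasts, differed by 2.96 (SE 0.67), COL12A1 by 1.95 (SE 0.40) and CCN4, a secreted matrix protein of the Wnt pathway, by 1.02 (SE 0.31), with 1.60 from its probe farthest from the reference. The fibroblast list, which shares 4 genes with it, was also higher, with a median of 0.32 and an adjusted p of 0.0171 (adjusted p = 0.534 with an estimated correlation), and its call was lost without tumor specimen A or E or normal specimen A or D, with adjusted p up to 0.177. Its median was 0.20 without tumor specimen A, 0.12 without tumor specimen E and 0.19 without normal specimen D. In it FBLN2, a matrix protein of vessel walls, differed by 0.88 (SE 0.25), while SFRP1, a secreted Wnt antagonist, differed by -2.75 (SE 0.76). Matrix proteases and their inhibitors had a median of 0.11 and an adjusted p of 0.0107 (adjusted p = 0.379 with an estimated correlation), a call lost without tumor specimen A or E (adjusted p up to 0.0822) and with each probe on its own (adjusted p 0.0919). The median was 0.0455 without tumor specimen E and 0.18 without tumor specimen D. ADAM8 differed by 1.46 (SE 0.42), MMP10 by 1.04 (SE 0.29) and ADAMTS5, which degrades aggrecan, by -1.84 (SE 0.54).

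The vascular basement membrane list had a median of 0.18 and an adjusted p of 0.0260 (adjusted p = 0.270 with an estimated correlation), and its call was lost without tumor specimen E or normal specimen A (adjusted p up to 0.148), under quantile normalization (0.0553) and on the repeat arrays alone (0.0579). The median was 0.29 without tumor specimen A. Over the list alone 3 of its 19 members passed as higher and 1 as lower. LAMA4, a laminin chain of endothelial basement membranes, differed by 0.79 (SE 0.16) and NID2, which links laminin to collagen IV, by 1.79 (SE 0.45), whereas LAMC1, the laminin gamma-1 chain, differed by -1.23 (SE 0.37). The probe of LAMA4 farthest from the reference gave 1.32 (adjusted p 0.0938).

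Endothelial markers stood somewhat higher in the tumor vessels. The pan-endothelial list had a median difference of 0.24, with 25 of 31 members higher, and an adjusted p of 0.000599 (adjusted p = 0.378 with an estimated correlation). The median was 0.16 without tumor specimen A and 0.14 without normal specimen D. Its members with the smallest p were CLDN14 (1.29, SE 0.36), PLVAP, a protein of endothelial diaphragms (0.61, SE 0.18), PECAM1 (1.46, SE 0.57) and ROBO4 (0.79, SE 0.32), and 0 members passed over the list alone. The list of tumor endothelial markers had a median of 0.19 and an adjusted p of 0.00421 (adjusted p = 0.209 with an estimated correlation), with 2 of 27 members passing over the list alone, both higher. Its median was 0.30 without tumor specimen C, and over all alternatives it ran from 0.13 to 0.50. One of its members was ANGPT2, a destabilising ligand of the TEK receptor, which differed by 0.88 (SE 0.22), while CXCR4, a chemokine receptor, differed by -1.47 (SE 0.51). Angiogenic ligands and receptors were not called (adjusted p 0.195). Their members with the smallest p went both ways: HEY2, a Notch target gene, differed by -1.42 (SE 0.33), HEYL by 1.55 (SE 0.47) and the netrin receptor UNC5B by 1.61 (SE 0.43). Capillary lipid handling was not called (adjusted p 0.608), and its members CAV1 and CAV2, which form caveolae, differed by -0.80 (SE 0.26) and -0.64 (SE 0.17), while the fatty acid transporter CD36 differed by 0.83 (SE 0.31). The difference of CAV1 was -0.12 under quantile normalization (adjusted p 0.922), -0.34 at equal array spread and -0.47 on the first arrays alone. Endothelial leukocyte adhesion and antigen presentation was not called either (adjusted p 0.775). CX3CL1, a membrane-bound chemokine, differed by -1.20 (SE 0.33). The probe farthest from the reference gave a wider difference than the mean of the probes for CX3CL1 (-3.30), HEY2 (-2.39), CD36 (2.01), ROBO4 (1.496) and CAV2 (-0.996).

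Interferon response genes had a median difference of 0.48, with 29 of 36 members higher and an adjusted p of 6.04e-06 (adjusted p = 0.378 with an estimated correlation). The median was 0.24 without tumor specimen E. The list mean was 1.496 in tumor specimen E, 1.09 in C, 0.54 in A, 0.28 in B and 0.16 in D, against 0.13 to 0.27 in normal vessels. CXCL9, a T cell chemokine induced by interferon gamma, had a log2 ratio of 3.21 ± 1.54 (SD, n = 5) in tumor and 0.56 ± 0.27 (SD, n = 5) in normal vessels and was the 1 member that passed over the list alone. XAF1 differed by 1.44 (SE 0.45), IFITM1 by 1.09 (SE 0.36) and IRF7, a regulator of type I interferon, by 0.96 (SE 0.31), with 2.01 from its probe farthest from the reference. Leukocyte lists were called higher as well. The lymphocyte and plasma cell list had a median of 0.18 and an adjusted p of 0.00472 (adjusted p = 0.582 with an estimated correlation), a call lost without tumor specimen A (adjusted p 0.251, median 0.0266), and its median was 0.31 without tumor specimen C and 0.29 without tumor specimen D. CCR7, the receptor of CCL19, differed by 2.13 (SE 0.67), the T cell marker CD2 by 1.97 (SE 0.72) and granzyme A, GZMA, by 1.83 (SE 0.63). The myeloid list had a median of 0.20 and an adjusted p of 0.0158 (adjusted p = 0.534 with an estimated correlation), a call lost without tumor specimen A or E (adjusted p up to 0.148), at equal array spread (0.134) and on the first arrays alone (0.0570). Its median was 0.33 without tumor specimen C, 0.11 without tumor specimen E and 0.12 without normal specimen B. S100A8, a calcium-binding protein of neutrophils, differed by 2.67 (SE 0.87).

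Ribosomal protein and immediate-early genes stood lower in the tumor vessels. Of 66 ribosomal protein genes 64 were lower, with a median of -0.79 and an adjusted p of 5.64e-24 (adjusted p = 0.209 with an estimated correlation), and 40 passed over the list alone. RPS9 differed by -1.65 (SE 0.31), RPL4 by -1.23 (SE 0.24) and RPL41 by -1.11 (SE 0.22). The list mean was -0.88 ± 0.34 (SD, n = 5) in tumor and -0.11 ± 0.10 (SD, n = 5) in normal vessels, and the groups did not overlap (exact permutation p = 0.00794, 2-sided, the smallest that 252 arrangements allow; 0.0825 after Benjamini-Hochberg adjustment over the 26 lists). Immediate-early genes, which cells and handled tissue switch on within minutes of a stimulus, had a median of -0.88, with 32 of 34 lower and an adjusted p of 1.71e-13 (adjusted p = 0.260 with an estimated correlation), and 17 passed over the list alone. Their list mean was 0.96 ± 0.43 (SD, n = 5) in tumor and 2.18 ± 0.49 (SD, n = 5) in normal vessels (exact permutation p = 0.00794, 0.0825 after adjustment). The chemokine gene CXCL2 differed by -3.21 (SE 0.67), ZFP36, which shortens the life of cytokine mRNA, by -2.44 (SE 0.48) and KLF6 by -1.48 (SE 0.29). Oxidative phosphorylation genes had a median of -0.21 and an adjusted p of 0.0475 (adjusted p = 0.534 with an estimated correlation), and 1 of 47, SDHD (-0.68, SE 0.14, and -0.38 under quantile normalization), passed over the list alone. That call was lost when tumor specimen A, B, D or E or normal specimen A, B, C or D was left out (adjusted p up to 0.175). It was also lost when each array was centred on its median (0.0529), at equal array spread (0.577), on the first arrays alone (0.226), with all 20 arrays (0.0717) and with the features of larger SD (0.130), and under quantile normalization the list tested in the other direction with a median of 0.0069 (adjusted p 0.811).

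Markers of the basal and myoepithelial cells that line normal ducts were lower in the tumor vessels, with a median of -0.92, 14 of 16 members lower and an adjusted p of 7.98e-07 (adjusted p = 0.284 with an estimated correlation). Over the list alone 9 members passed, all lower. P-cadherin, CDH3, differed by -1.63 (SE 0.52), PERP by -1.28 (SE 0.39), DST by -1.02 (SE 0.31) and MME by -0.65 (SE 0.21). The probe farthest from the reference gave -2.87 for DST and -0.67 for PERP. The list mean was 1.02 ± 0.38 (SD, n = 5) in normal and 0.02 ± 0.74 (SD, n = 5) in tumor vessels. In tumor specimens B and D it was 0.61 and 1.01, inside the normal range of 0.44 to 1.39, and in A, C and E it was -0.68, -0.41 and -0.43. The luminal epithelial list was not called (adjusted p 0.608), and its members moved apart, with KRT15 at -3.38 (SE 1.04) and MLPH at 1.35 (SE 0.32), or 2.17 by the MLPH probe farthest from the reference. Mural cells, the pericytes and smooth muscle of vessel walls, were not called as a list (adjusted p 0.151), and over the list alone 3 of 24 members passed, all lower. ACTG2, a smooth muscle actin, had a log2 ratio of 1.20 ± 2.39 (SD, n = 5) in tumor and 5.25 ± 0.73 (SD, n = 5) in normal vessels, and ACTA2 differed by -2.33 (SE 0.52). In tumor specimens B and D ACTG2 was 3.105 and 4.382, and in A, C and E it was -0.618, -0.851 and -0.026. The basal list mean divided the tumor specimens in the same way. The mural list was called lower without tumor specimen D (adjusted p 0.00787), without normal specimen D (0.0454), at equal array spread (0.0216), with all 20 arrays (0.00721) and with the features of larger SD (0.00365). These calls used the preset correlation. In the main fit the camera adjusted p of the mural list with an estimated correlation was 0.658.

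**Figure D2:**
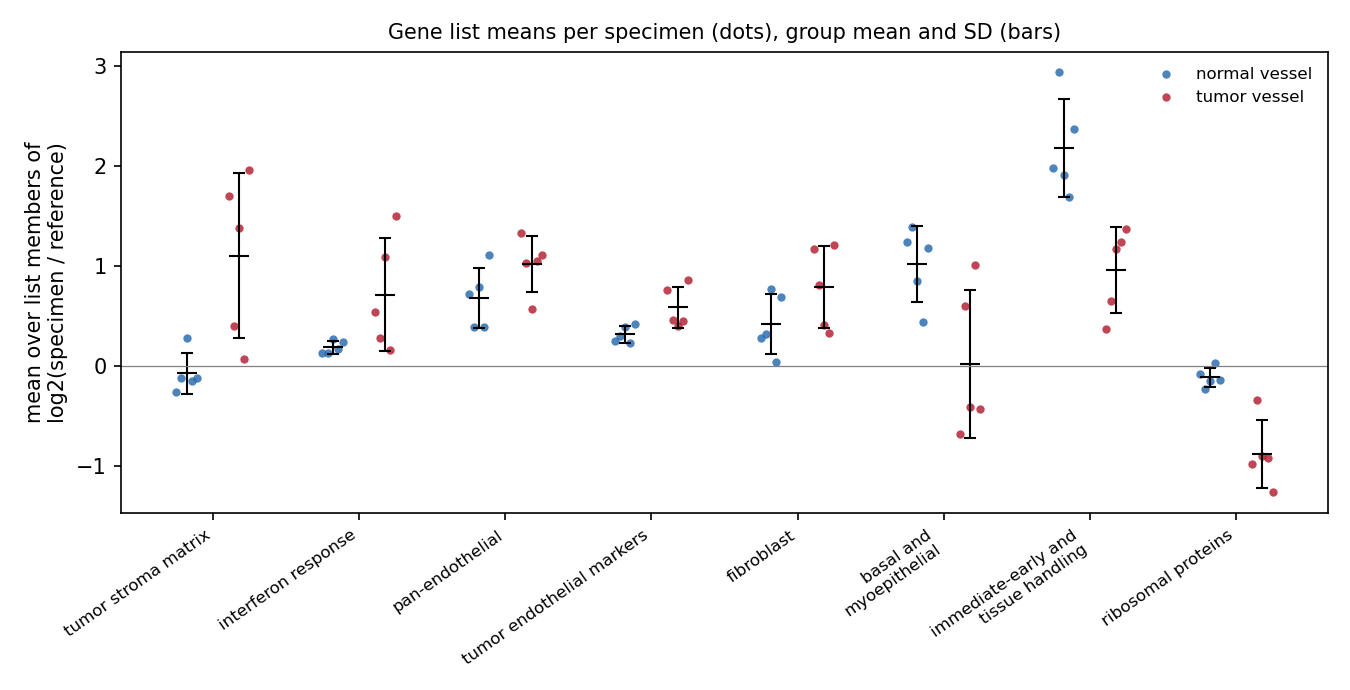
Mean log2 ratio over the members of 8 gene lists (vertical axis) in each specimen. Each dot is 1 specimen and the bars give the group mean and SD over 5 specimens. The ribosomal list runs from -0.88 ± 0.34 in tumor to -0.11 ± 0.10 in normal vessels and the matrix list from 1.11 ± 0.83 in tumor to -0.07 ± 0.21 in normal vessels.

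The remaining lists were not called by camera. Their adjusted p was 0.104 for Wnt signaling, 0.285 for adipocyte markers, 0.285 for erythrocyte and platelet markers, 0.732 for mast cell markers, 0.732 for the cell cycle, 0.732 for sphingolipid metabolism, 0.786 for JAK-STAT signaling and 0.786 for hypoxia and glycolysis. The cell cycle list was called higher in tumor vessels under 2 other scalings, quantile normalization (adjusted p 2.08e-06, median 0.38) and equal array spread (adjusted p 0.00119, median 0.22), and hypoxia and glycolysis under quantile normalization (adjusted p 0.0439, median 0.15), while Wnt signaling passed as lower without normal specimen B (adjusted p 0.0359) and with all 20 arrays (adjusted p 0.0367). These calls used the preset correlation. In the main fit the camera adjusted p with an estimated correlation was 0.926 for the cell cycle, 0.926 for hypoxia and glycolysis and 0.2835 for Wnt signaling. The Wnt list mean was 0.19 ± 0.13 (SD, n = 5) in tumor and 0.41 ± 0.11 (SD, n = 5) in normal vessels (exact permutation p = 0.0159, 0.0825 after adjustment). FZD4, a Wnt receptor that also binds norrin in vessels, differed by 0.91 (SE 0.18) and the transcription factor gene MYC by -0.75 (SE 0.19), with -2.14 from the MYC probe farthest from the reference. Hemoglobin beta, HBB, was lower in tumor vessels by value, at 2.55 ± 0.69 (SD, n = 5) against 5.32 ± 2.14 (SD, n = 5), and its difference did not pass (adjusted p 0.238).

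SFRP2, JAK3 and SMPD3 are recalled as genes that the study followed up, and since they were picked on these samples their direction is no independent evidence. All 3 were higher in tumor vessels by value and did not pass. SFRP2, a secreted modulator of Wnt signaling, differed by 1.33 (SE 0.46, adjusted p 0.285), JAK3, a kinase of cytokine receptors, by 0.67 (SE 0.25, adjusted p 0.326) and SMPD3, a neutral sphingomyelinase, by 1.10 (SE 0.32, adjusted p 0.208). Their probes did not behave alike. The probe with the largest difference gave 2.34 (SE 0.66) for SFRP2, 2.02 (SE 0.49) for JAK3 and 2.19 (SE 0.56) for SMPD3. The other probes of JAK3 gave 0.007 (SE 0.195) and -0.002 (SE 0.184), and the other probe of SMPD3 gave 0.00 (SE 0.14). The other probes of SFRP2 were higher too but by less, at 0.76 (SE 0.42) and 0.88 (SE 0.37). SMPD4, a related sphingomyelinase gene, differed by 1.05 (SE 0.19, adjusted p 0.0960).

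The technical repeats were closer to each other than different specimens were. Across features, r between the arrays of a specimen ran from 0.900 to 0.970 with a median of 0.938, against a median of 0.786 between arrays of different tumor specimens, 0.791 between arrays of different normal specimens and 0.760 between tumor and normal. These r are across features, which are not replicates. Tumor specimen B had its highest r, 0.903, with normal specimen A, and the next, 0.896, with tumor specimen D. The median SD over features was 0.23 between arrays of a specimen and 0.34 between specimens of a group. With the arrays averaged, r within groups exceeded r between groups by 0.0443 (exact permutation p = 0.00794, 1-sided). The median SD between specimens was 0.31 for tumor and 0.32 for normal vessels, a difference below what relabelling gave (exact permutation p = 0.754, 2-sided).

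**Figure D3:**
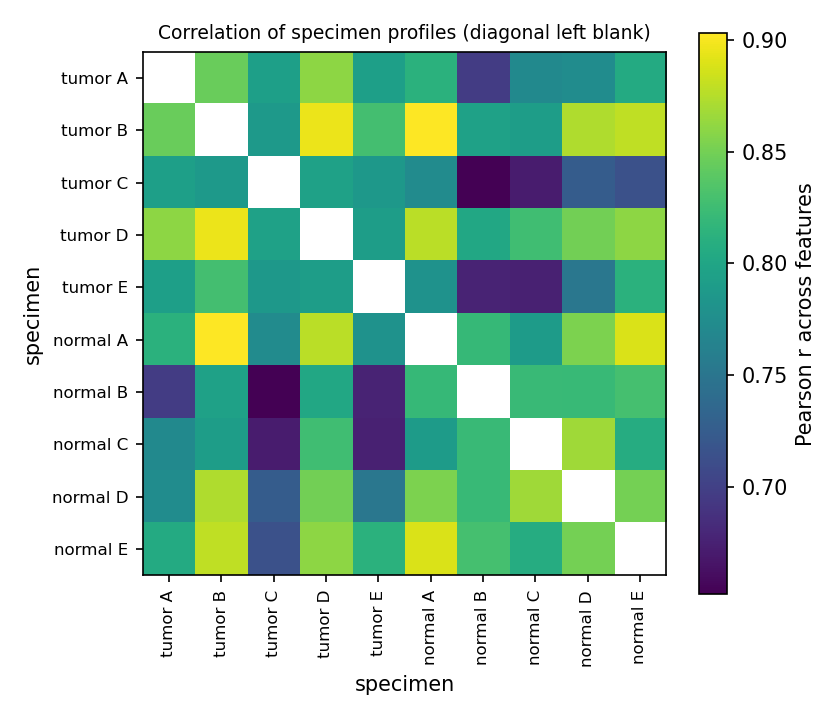
Pearson r across features between the specimen profiles, with specimens on both axes and r as colour. Pairs of tumor specimens lie between 0.786 and 0.896, pairs of normal specimens between 0.790 and 0.889, and tumor against normal between 0.652 and 0.903.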

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

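The tests on ribosomal against oxidative phosphorylation genes and on the share of endothelial cells were chosen after the results were seen, and the other tests are recorded as chosen before. The ribosomal, immediate-early and matrix patterns that they weigh were worded with a direction. Their tests are therefore not taken as blind to the list results. Of 294 groups of 5 specimens examined, 14 held a specimen far from the other 4 of its group, where chance gives about 14.7. The value is the gap of that specimen over the range of its group. For list means in tumor vessels it was 0.770 for luminal epithelial, 0.827 for sphingolipid metabolism and 0.793 for hypoxia and glycolysis genes. For list means in normal vessels it was 0.741 for tumor stroma matrix and 0.775 for vascular basement membrane genes. For single genes in tumor vessels it was 0.745 for ARHGEF17, 0.726 for HPGDS and 0.750 for MMP10. For single genes in normal vessels it was 0.794 for RNF150, 0.879 for CCN4, 0.752 for ANGPT2, 0.783 for CTSG, 0.778 for KIF23 and 0.763 for CA12.

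Chance can be excluded neither for the number of features called nor for the number of lists called. Over 100 of the 126 splits of the 10 specimens, 5 called at least as many features as the real split, the real one included. The real split called 1 feature and the highest other split 2. At an unadjusted p under 0.05 the real split counted 3886 features, the median of the other splits 1277 and the highest 4972, and 5 of the 100 splits counted as many as the real one, itself included. The split with 4972 kept 4 tumor specimens on 1 side. For gene lists, 13 of the 100 splits called at least the 13 lists of the real split, and the highest other split called 17. The median of the other splits was 7 lists with the preset correlation, so list calls at that setting are common in these specimens whatever the grouping.

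The first pattern weighed is the lower level of ribosomal protein genes in tumor vessels. A difference in the spread of the arrays is argued against as the whole cause, because after each array was scaled to the same spread the list mean still differed by -0.70 (SE 0.15). A lower yield of small housekeeping transcripts would lower oxidative phosphorylation genes as much, but the difference between the groups was more negative in the ribosomal list, by -0.59 (SE 0.20, exact permutation p = 0.0317). Both list means were known when that test was chosen, and an equal fall of the lists is assumed, so a lower yield is not excluded. What also stays open is a difference between the groups in the tissue, its processing or its vessels, which the design does not separate, and the biological difference between tumor and normal vessels was not tested apart from these.

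The second pattern is the lower level of immediate-early genes in tumor vessels. If basal epithelial cells in the normal specimens were its source, the list would follow the basal markers within groups, and the group difference would vanish with these markers as a covariate. The difference was -1.22 (SE 0.29) before and -0.92 (SE 0.40) after. Over 10 specimens with group means removed, r was 0.378 (permutation p = 0.301) and rho 0.430 (permutation p = 0.277), the 1 relation examined, and r was 0.112 without the 2 specimens farthest from the median. The mark set beforehand against this source was a difference more than 2 SE below 0 with the covariate, which was met narrowly. The basal list mean itself differs between the groups, and r is imprecise at 10 specimens. Basal carry-over is therefore not excluded as the cause. The time between surgery and freezing, which no source used here gives, also stays open beside the biology of the vessels.

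The third pattern is the higher level of tumor stroma matrix genes. Carry-over of fibroblasts as such would raise all their abundant transcripts, yet the mean of the 22 fibroblast markers outside the matrix list differed by 0.11 (SE 0.20, exact permutation p = 0.571). DCN differed by -0.03 (SE 0.52) and LUM by 0.47 (SE 0.33). The matrix list exceeded those 22 markers by 1.07 (SE 0.35, exact permutation p = 0.0238). The markers went both ways, with SFRP1 at -2.75 (SE 0.76), SFRP2 at 1.33 (SE 0.46) and FBLN2 at 0.88 (SE 0.25). SFRP1 lowers their mean, so that mean does not show that each marker stayed level. A lower share of endothelial cells in the tumor vessels would raise the markers of every other cell type alike. The matrix list mean differed by 1.18 (SE 0.38), the basal by -1.001 (SE 0.37) and the mural by -0.57 (SE 0.24). Smooth muscle and myoepithelium share CNN1 and MYLK of the mural list, and ACTG2 divided the tumor specimens as the basal list did. The basal and mural falls may therefore not be separate evidence. Lymphocyte (0.37), full fibroblast (0.37), myeloid (0.33) and adipocyte (0.11) means were higher, and mast cell (-0.40), erythrocyte and platelet (-0.28) and luminal (-0.08) means lower. The mast cell mean rests mainly on KIT, with a list median of -0.01, so it does not show a fall of that cell type. In the erythrocyte and platelet list HBB differed by -2.77 (SE 0.86), and the list median was -0.18. The difference between the groups was higher in the matrix than in the basal list by 2.18 (SE 0.73, exact permutation p = 0.0238), a contrast chosen with both means known. That contrast rests on tumor specimens A, C and E. In tumor specimens B and D the matrix mean (0.40 and 0.07) lay below the basal mean (0.61 and 1.01), as in every normal specimen. The pan-endothelial list mean was higher by 0.34 (SE 0.18). A lower share alone would not move the lists both ways, but one beside other changes in cell types is not excluded. Activated fibroblasts or mural cells in the captured tissue, or the vessels themselves, stay open as sources and were not tested.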

How the results depend on the processing

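The alternative with unnamed spots left out was chosen after seeing the data, called 1 feature and 13 lists, and changed none of the counts. The others were planned, and where a count moved the cause was not tested unless stated. The number of called features was 1, with 1 higher and 0 lower in tumor vessels. It was 2 under quantile normalization (0 higher, 2 lower). It was 0 at equal array spread, on the first arrays alone, by an ordinary linear model and at an adjusted p under 0.01. In each of these 0 were higher. An exact rank test also called 0 features, but with this number of specimens it could not call any. Its count therefore does not show a dependence on the choice of test. The number of called features was 130 at an adjusted p under 0.10 (37 higher, 93 lower), as a wider threshold must give. With only the features of larger SD it was 70 (25 higher, 45 lower), where fewer features were tested. All 20 arrays with the specimen as a random block gave 1284 (477 higher, 807 lower), in a fit whose residual degrees of freedom count arrays and not specimens. Leaving out 1 specimen gave 0 to 121 called features, 0 to 30 higher and 0 to 91 lower, with 121 without tumor specimen B and 4 without tumor specimen D. The difference of ZNF177 stayed above 0 in every alternative run, from 1.51 to 1.98.

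The letters A to E are shared by tumor and normal specimens. Of the 5 same-letter pairs, 1 had a correlation of deviations from the group means above 0.1, and 1 of 5 tumor specimens correlated best with its own letter, so the letters were not taken as a pairing. The replicate block gave 0 called features, 0 higher and 0 lower, and ended no call of a list.

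The number of called lists was 13, with 9 higher and 4 lower. It was 0 (0 higher, 0 lower) with an estimated correlation and 1 (0 higher, 1 lower) by fry. Leaving out 1 specimen gave 8 to 13 called lists, 5 to 9 higher and 3 to 4 lower. Over the 22 settings other than these set tests, the calls of the pan-endothelial, tumor stroma matrix, tumor endothelial, basal, interferon, immediate-early and ribosomal lists were never lost. Of 623 list values under alternatives, 532 kept direction and side of the threshold, 54 lost the call, 9 gained one and 28 tested in the other direction. Those 28 belong to lists without a call apart from oxidative phosphorylation, whose median was 0.0069 under quantile normalization. The hypoxia median was 0.15 under quantile normalization, 0.018 at equal array spread, 0.022 on the first arrays, -0.10 with all 20 arrays, -0.058 with features of larger SD, and -0.24 to 0.012 without 1 specimen. The cell cycle median was -0.078 on the repeat arrays, -0.076 by single probes, -0.19 with array weights and -0.14 to 0.18 without 1 specimen. The luminal median was 0.068 on the first arrays, 0.11 by single probes and -0.23 to -0.010 without 1 specimen. Leukocyte adhesion had 0.0018 at equal array spread and -0.068 to 0.12 without 1 specimen. JAK-STAT signaling had -0.14 with features of larger SD and -0.13 to -0.045 without 1 specimen. Capillary lipid handling had 0.0097 with array weights and -0.17 to -0.0011 without 1 specimen. Without 1 specimen, mast cell markers ran from -0.075 to 0.019 and sphingolipid genes from -0.059 to 0.045. Where a median kept its sign, it was the direction of the camera test that turned.

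Of 2630 values of 120 genes covered by the naming rule, 2 turned sign, MCM2 at 0.026 under quantile normalization and CDC20 at 0.042 on the first arrays, 12 lost a call, all of ZNF177, and 123 gained one, 79 of them with all 20 arrays. The difference moved by over 1.5 times in at least 1 alternative for 48 of the 120 genes, 16 under quantile normalization, 11 at equal array spread, 22 by single probes and 13 without 1 specimen. The separation of the groups kept its direction and side of the threshold in all alternatives run, from 0.0308 to 0.0577 without 1 specimen. The difference in spread was 0.037 with features of larger SD and ran from -0.036 to 0.018 without 1 specimen, below the threshold throughout. Agreement of the repeats moved by less than its SD. No brightness was analysed here, so it is open which values lie near background.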

Other observations

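Some members of the mast cell, mural and luminal lists had wide gaps between the vessels, and none of them passed over all features. KIT, a receptor of mast cells and of luminal progenitors in the breast, had a log2 ratio of 2.18 ± 2.25 (SD, n = 5) in tumor and 6.12 ± 0.70 (SD, n = 5) in normal vessels. It was the 1 member of the mast cell list that passed over the list alone, while the mast cell enzyme gene HDC differed by 0.58 (SE 0.52) in the other direction. The list's median was -0.01 and its mean difference -0.40, so that mean rests mainly on KIT. The difference of HDC was 0.21 without tumor specimen E, 0.26 without normal specimen A and 0.34 at equal array spread. CNN1 and MYLK, which smooth muscle and myoepithelium share, differed by -2.65 (SE 0.89) and -2.19 (SE 0.64). In tumor vessels the SD between specimens was 2.25 for CNN1 and 2.69 for KRT15, against 0.57 and 0.35 in normal vessels.

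Members of the JAK-STAT list went both ways by value, with 4 higher and 3 lower in tumor vessels at an unadjusted p under 0.05. JAK3 was among the higher ones. Among the lower ones, the inhibitor genes SOCS5 and SOCS6 differed by -0.67 (SE 0.18) and -0.93 (SE 0.32) and the cytokine receptor gene LIFR by -0.42 (SE 0.15). In the glycolysis list GPI, a glycolytic enzyme, differed by 1.06 (SE 0.26), while ENO1 differed by -0.70 (SE 0.28) and MXI1, an antagonist of MYC, by -0.94 (SE 0.26). In the cell cycle list the smallest p belonged to KIF23, at 0.76 (SE 0.35, adjusted p 0.421). The difference of ENO1 was -0.06 under quantile normalization (adjusted p 0.952), -0.29 at equal array spread and -0.35 on the first arrays alone. That of LIFR was -0.21 and that of KIF23 1.22 under quantile normalization, KIF23 had 0.43 without tumor specimen C, and the SOCS5 probe farthest from the reference gave -0.29. None of these differences passed.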
